A study of Homo sapiens with 6 samples.

How the data were processed

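Total RNA of 6 libraries, 3 of each line, was sequenced after preparation with a stranded total RNA kit, per the labels' protocols. The submitters' processing notes name cutadapt, STAR and featureCounts and the builds GRCh37 and hg19, with no versions, roles or order. The gene models, the strand setting and the normalization tool are not given in the sources used here. The values deposited by the authors are on a log2 scale, and the joined table holds the same values as the files of single samples. That the scale is log2(RPKM + 1) was worked out from the deposited values. Among 2914 low genes, 459 share 1 ratio between WT replicates 1 and 2 when the base is 2, and 5 or 3 do when the base is e or 10, as whole reads divided by length and library total would give.

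Whole reads and gene lengths were recovered from the deposited values for 18291 of 18291 genes with any read, with 0.001 as the tolerance for a whole number. On simulated reads of 2935 genes, 96.66% of genes came back exactly and 100% exactly or divided by a common factor. The library totals implied by the deposited values were 0.957 to 1.03 times the recovered reads, so the authors' values hold a scaling factor whose method is not given in the sources used here. Recovered reads per library ranged from 27882045 to 109252512. Mitochondrial transcripts took 5.3 to 8.2% of them. Chi-square per degree of freedom between replicates of a group was 72.8 to 288.3, above sampling noise, so none was taken for a repeat deposit of another. This does not show that the libraries are independent, and they were counted as the labels give them.

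The tests, gene lists, rule for named genes and alternatives not said to be added later were fixed before the data were examined, and the tests assumed raw counts. As the deposited values are not counts, the test fitted was limma 3.58.1 in R 4.3.3, with an intensity trend and robust variances, on the deposited log2(RPKM + 1), with group as the only term. Genes needed at least 0.169 CPM of recovered reads, which is 10 reads at the median depth, in 3 libraries, and 15 reads in total, which kept 14139 genes and left out 4152 with fewer reads. Adjusted p is by the Benjamini-Hochberg method with a threshold of 0.05, and tests are two-sided. A fold change on log2(RPKM + 1) understates the change of low genes, so ratios of mean RPKM and, for some genes, fold changes from limma-voom on recovered reads are given beside it. DESeq2 and edgeR were not used.

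The 28 gene lists were tested with limma's camera against all other genes (preset correlation 0.01, adjusted over the lists, at least 5 tested members). The rule for named genes takes BRCA1, CCL5, CXCL10, MB21D1, TMEM173, IFNB1, CD274 and VEGFA whatever they do. It adds the 8 highest and 8 lowest called genes by log2 fold change with a mean of at least 5 CPM, groups that do not overlap and a gene symbol. It also takes up to 4 called members of each list with the largest change. Some genes the rule takes are not reported here. On simulated reads with known changes, 14160 genes were tested, 78% of genes changed 2-fold and 96% of those changed 4-fold were called, and 3.7% of calls were unchanged genes. In that simulation genes varied independently, without deviations that genes of a library share.

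Settings compared with the one above were other scalings, filters, limma-voom, a test against a 1.5-fold change, an adjusted p of 0.01, the replicate number as a block, each library left out, short and abundant RNA classes left out, and other list tests. Added after seeing the data were a pseudocount of 0.1 RPKM, reads thinned to the shallowest library, removal of each library's trend on GC content, and removal of the median of up to 60 neighbouring genes. GC content came from GENCODE transcripts and was known for 98.9% of tested genes. Gene order came from a RefSeq table of another assembly, GRCh38.p14, used only for names and for which genes neighbour each other, so no positions are given, and placed 13925 of the tested genes (98.5%). In order along this table, 266 windows of at least 50 genes were formed. On simulated reads with 5 of 266 windows raised 1.5-fold over 13925 placed genes, all 5 and no other were found. The simulated genes varied independently, so this does not measure false windows where neighbouring genes share deviations between libraries. Figures were drawn with matplotlib 3.10.9.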

Results

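RNA was sequenced from UWB1.289, an ovarian carcinoma cell line with a deleterious mutation in BRCA1, and from an isogenic line in which wild-type BRCA1 was expressed. BRCA1 acts in the repair of DNA breaks by homologous recombination. There were 3 libraries of the mutant line (MUT) and 3 of the line with wild-type BRCA1 (WT). The files listed 20268 genes, of which 1977 were at 0 in all 6 libraries. The reads recovered from the deposited values were 59577280, 58960247 and 65845740 in WT replicates 1 to 3, and 109252512, 45469464 and 27882045 in MUT replicates 1 to 3. The deepest library thus held 3.92 times the reads of the shallowest. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. All comparisons are MUT relative to WT, with group values given as mean RPKM ± SD (n = 3 libraries per group).

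The comparison asked which transcripts differ between cells that lack functional BRCA1 and cells in which it was restored, with the interferon response and DNA sensing named in the series title. BRCA1 transcript itself was 24.97 ± 6.88 RPKM in WT and 3.57 ± 0.428 RPKM in MUT, 6.99-fold lower. Its values were 17.3, 27.1 and 30.5 RPKM in the WT libraries and 3.65, 3.96 and 3.11 RPKM in the MUT libraries, in the direction the labels give. The log2 fold change of BRCA1 was -2.47 (SE 0.22, limma adjusted p = 0.00231). Values per gene do not separate the introduced from the endogenous transcript.

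Of the called genes that the rule for named genes takes by fold change, the 8 highest in MUT were TM4SF1, EHF, CYP2S1, PTX3, COL6A1, MMP2, COL6A2 and IFI16. TM4SF1, a tetraspanin-like membrane protein, rose from 2.17 ± 0.395 to 54.1 ± 11.04 RPKM, and EHF, an epithelial ETS transcription factor, from 0.365 ± 0.128 to 19.7 ± 5.14 RPKM. The 8 lowest were NID2, PTGER2, MYBPC2, PASD1, NPR3, CLDN6, SMR3B and ABCA4. NID2, a basement membrane protein, fell from 133 ± 38.4 to 9.49 ± 1.71 RPKM, and the tight junction protein CLDN6 from 22.1 ± 2.64 to 1.59 ± 0.468 RPKM. PTGER2, a prostaglandin E2 receptor, was 25.1-fold lower and PASD1 was 71.8-fold lower in MUT. TM4SF1 lies among neighbouring genes that were higher in MUT and ABCA4 among neighbours that were lower, and both kept their calls with the neighbours' median removed (adjusted p = 0.000247 and 0.000383).

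limma called 1673 of 14139 tested genes at an adjusted p under 0.05, 957 higher and 716 lower in MUT. The number of calls fell when a library was left out, which also leaves fewer libraries. It was 844, 783 and 513 without WT replicates 1, 2 and 3, and 1264, 1239 and 293 without MUT replicates 1, 2 and 3. MUT replicates 1 and 2, the pair left without MUT replicate 3, were the least alike within a group (Pearson r 0.957, other pairs at least 0.983). A call lost without MUT replicate 3 thus need not rest on that library. All 293 genes called without MUT replicate 3 were also called with all 6 libraries. Of the named genes above, COL6A2 lost its call without WT replicate 3 and without MUT replicate 3 (adjusted p up to 0.0661), and MYBPC2 and SMR3B lost theirs without MUT replicate 3 (adjusted p = 0.058 and 0.0722). Without a WT library fewer than 3 of that line are left. SMR3B, near 0 in MUT, then could not reach the minimum CPM in 3 libraries and was not tested.

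**Figure D1:**
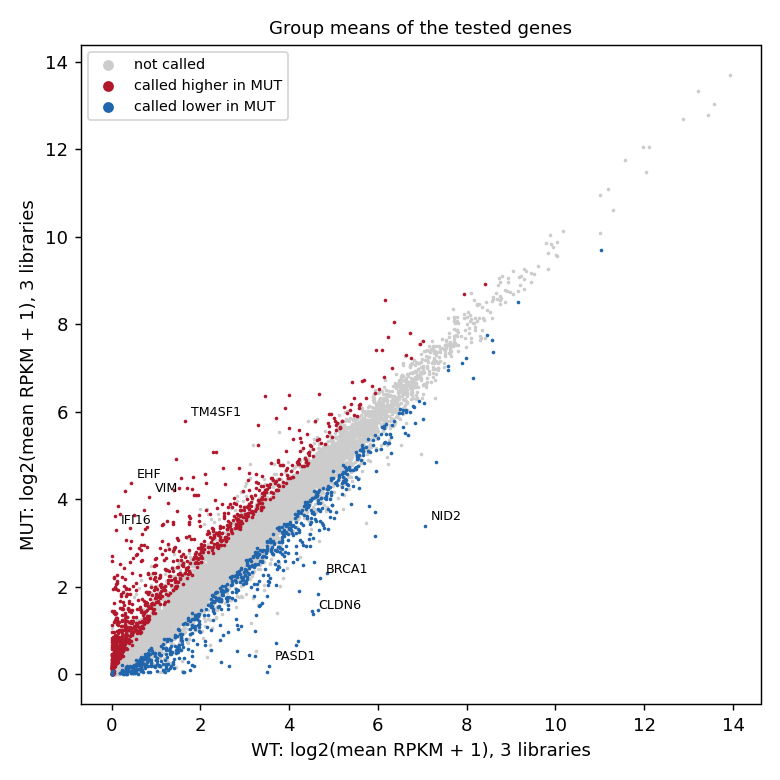
Mean expression of each tested gene in WT (x axis) and MUT (y axis), both as log2(mean RPKM + 1) over 3 libraries; red points were called higher in MUT (957 genes), blue points lower (716 genes) and grey points were not called. TM4SF1, EHF, VIM and IFI16 lie far above the diagonal, and NID2, CLDN6, PASD1 and BRCA1 far below it.

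Interferon-stimulated genes, the transcripts that cells raise in response to interferon, were higher in MUT as a group by camera (adjusted p = 9.47e-08), a call that was lost with an estimated correlation between genes (adjusted p = 0.467). Of 57 tested members, 18 rose, 2 fell and 37 were not called, and 48 had a log2 fold change above 0. IFI16, a sensor of DNA, rose from 0.0647 ± 0.0308 to 8.85 ± 0.168 RPKM, and IFI44 from 0.329 ± 0.165 to 9.18 ± 2.27 RPKM. IFITM2 and IFITM1, membrane proteins that restrict virus entry, rose 7.62-fold and 14.4-fold. BST2, which tethers virus particles, fell from 189.6 ± 20.98 to 122 ± 18.9 RPKM, and IFIT5 fell from 1.83 ± 0.198 to 1.04 ± 0.119 RPKM, and both lost their calls without each library in turn (adjusted p up to 0.148 and 0.166). BST2 and IFIT5 were named after their values were seen, as was the gene in the next sentence. ISG15 was 20.4 ± 7.03 RPKM in WT and 14.6 ± 13.8 in MUT, which did not pass the test (adjusted p = 0.498).

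The median log2 fold change of the interferon-stimulated genes was 0.48, and 0.82 on recovered reads, where low genes are not compressed. Adjusted over the list alone, 28 rose and 3 fell. The number of members that rose was 7 without WT replicate 1, 9 without WT replicate 2, 6 of 56 tested without WT replicate 3, 22 of 54 without MUT replicate 1, 14 of 53 without MUT replicate 2 and 5 of 53 without MUT replicate 3, and the camera adjusted p was at most 6.58e-06 without any 1 library. IFI16, IFI44, IFITM1 and IFITM2 kept their calls without any 1 library. The reads of close paralogs such as IFITM1 and IFITM2 could be split differently by another counting rule.

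Genes of cytosolic DNA sensing were not called as a group. The list holds sensors, signalling genes such as TBK1 and nucleases such as TREX1, which need not move in 1 direction. Of 22 tested members, 1 rose (IFI16) and 21 were not called (camera adjusted p = 0.344; adjusted over the list alone, 1 rose). By limma-voom and with no filter 2 were called higher, IFI16 and ZBP1, a sensor of nucleic acids in the Z form that was named after its values were seen. ZBP1 had 0, 0 and 2 reads in WT and 19, 8 and 6 in MUT (adjusted p = 0.246 on the deposited scale, 0.0135 by limma-voom and 0.0189 with no filter). The gene of cGAS, the enzyme that turns cytosolic DNA into a second messenger (MB21D1), was 9.98 ± 3.88 RPKM in WT and 9.44 ± 2.87 in MUT (log2 fold change -0.05, SE 0.29, adjusted p = 0.931). The gene of STING, its adaptor (TMEM173), was 3.51 ± 1.20 and 5.03 ± 0.745 RPKM (log2 fold change 0.44, SE 0.21, adjusted p = 0.222). Among genes of cytosolic RNA sensing, which are not all sensors, 3 of 13 rose: IFIH1, TRIM25 and DHX58 (camera adjusted p = 0.344; adjusted over the list alone, 3 rose). IFIH1, the sensor MDA5, rose from 3.59 ± 0.541 to 8.43 ± 2.40 RPKM. DHX58 rose 6.88-fold at a low level. IFI16, IFIH1 and DHX58 are also members of the interferon-stimulated list, so their calls here are not separate results. TRIM25 lies among neighbouring genes that were higher in MUT and was not called once their median was removed (adjusted p = 0.359). IFIH1 lost its call without any 1 WT library or MUT replicate 3 (adjusted p up to 0.115), TRIM25 without WT replicates 1 and 3 and MUT replicate 3 (up to 0.0727), and DHX58 without MUT replicate 3 (0.0543). Of 12 interferons and receptors, IL10RB and IFNAR2 rose (camera adjusted p = 0.627; over the list alone, 2 rose and 1 fell). With the neighbours' median removed neither IL10RB nor IFNAR2 was called (adjusted p = 0.102 and 0.149). IL10RB lost its call without each library and IFNAR2 without each but MUT replicate 2 (adjusted p up to 0.186 and 0.144). IFNB1 had 1, 0 and 0 reads in the WT libraries and 3, 2 and 2 in the MUT libraries and missed the read minimum. With no filter its log2 fold change was 0.07 (adjusted p = 0.0981).

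**Figure D2:**
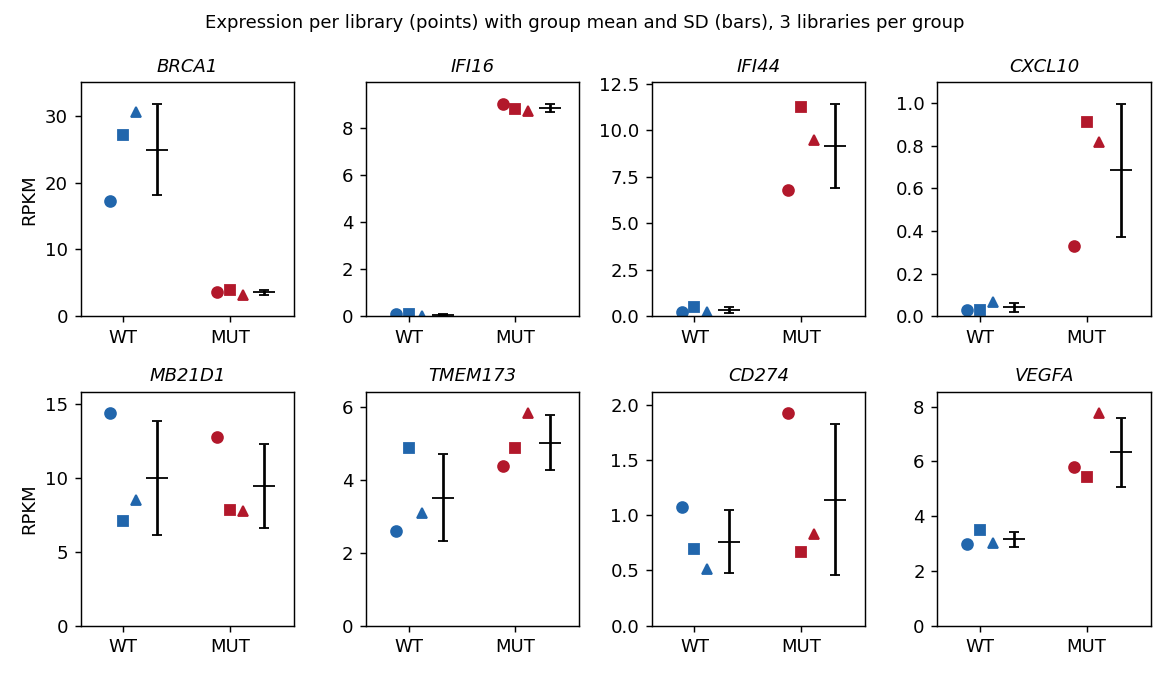
RPKM (y axis) of 8 genes in each library, with circles, squares and triangles for replicates 1, 2 and 3 of WT (blue) and MUT (red), and bars for the group mean and SD. BRCA1 lies between 17.3 and 30.5 RPKM in WT and between 3.11 and 3.96 in MUT, IFI16 and IFI44 are near 0 in WT, and the groups overlap for MB21D1, TMEM173 and CD274.

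Chemokines and cytokines were higher in MUT as a group by camera (adjusted p = 0.000177; with an estimated correlation, adjusted p = 0.467). Of 29 tested members 7 rose, 2 fell and 20 were not called. IL1A, an alarm cytokine, rose from 2.25 ± 0.377 to 18.3 ± 5.17 RPKM, and CSF1, the macrophage growth factor, from 2.64 ± 0.335 to 7.48 ± 0.698 RPKM. IL23A rose 3.34-fold. IL18, another inflammatory cytokine, fell from 69.4 ± 2.44 to 38.1 ± 6.29 RPKM, and IL15, named after its value was seen, from 0.863 ± 0.0735 to 0.486 ± 0.0963 RPKM. CXCL10, which attracts T cells, was low in both lines, with 2, 2 and 5 reads in WT and 43, 50 and 27 reads in MUT. Its log2 fold change was 0.68 (SE 0.14, adjusted p = 0.0265) on the deposited scale and 3.63 (SE 0.65) on recovered reads. CCL5 had 4, 5 and 9 reads in WT and 17, 20 and 6 in MUT and did not reach the minimum CPM in 3 libraries. With no filter its log2 fold change was 0.14 (adjusted p = 0.221). Adjusted over the list alone, 12 rose and 3 fell. CXCL10 lost its call without any 1 WT library (adjusted p up to 0.0857). Without any 1 MUT library fewer than 3 of that line are left, so CXCL10 could not reach the minimum CPM in 3 libraries and was not tested. IL18 lost its call without any 1 WT library or MUT replicate 3 (up to 0.0595), IL15 without each library but MUT replicate 2 (up to 0.181), and IL23A without WT replicate 3 or MUT replicate 3 (up to 0.0969). The number of members that rose was 3, 6 and 2 without WT replicates 1, 2 and 3, and 6, 5 and 2 of 26 tested without MUT replicates 1, 2 and 3. It was 4 of 22 with a filter of at least 1 CPM.

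Targets of NF-kB, a transcription factor of inflammation, were also higher in MUT by camera (adjusted p = 5.81e-07; with an estimated correlation, adjusted p = 0.241). Of 27 tested members 9 rose, none fell and 18 were not called. PTX3, a secreted pattern recognition protein, rose from 1.75 ± 1.48 to 29.4 ± 5.43 RPKM. Complement C3 rose from 1.19 ± 0.968 to 5.71 ± 0.495 RPKM, and NFKBIZ and BIRC3 rose 3.87-fold and 3.04-fold. Adjusted over the list alone, 15 rose. PTX3, which lies among neighbours that were higher in MUT, kept its call with their median removed and without any 1 library, and C3, NFKBIZ and BIRC3 lost theirs without MUT replicate 3 (adjusted p up to 0.0839 for C3). C3 also lost it without WT replicate 3 and NFKBIZ without WT replicates 1 and 2. The number of members that rose was 6, 7 and 5 without WT replicates 1, 2 and 3, and 7, 8 and 2 of 25 tested without MUT replicates 1, 2 and 3.

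The list of MHC class I antigen presentation, which also holds ligands of natural killer cells that do not present antigen, went both ways: 1 of 27 rose, 4 fell and 22 were not called. MICA and MICB, ligands of the NKG2D receptor of natural killer cells, fell from 25.8 ± 5.01 to 9.98 ± 1.19 RPKM and from 24.8 ± 0.571 to 10.3 ± 0.716 RPKM. The chaperone CANX fell from 250.5 ± 20.7 to 147.9 ± 8.66 RPKM, and HLA-G rose from 0.124 ± 0.0858 to 1.29 ± 0.0357 RPKM. HLA-F fell from 0.330 ± 0.0614 to 0.140 ± 0.0221 RPKM. B2M, HLA-B and HLA-C did not pass the test (adjusted p = 0.156, 0.901 and 0.423). HLA-F and these 3 genes were named after their values were seen. The list's median was 0.04, its mean -0.02 and its camera direction lower (adjusted p = 0.886), and over the list alone 1 rose and 5 fell. MICA, MICB and CANX lie among neighbours that were lower in MUT, and with the neighbours' median removed MICA and MICB kept their calls (log2 fold changes -0.98 and -0.91) and CANX did not (adjusted p = 0.401). In that setting 2 members of the list rose and 2 fell. MICA lost its call without MUT replicate 3 (adjusted p = 0.0533), CANX without WT replicate 3 or MUT replicate 3 (up to 0.0663) and HLA-F without each library in turn (up to 0.144). Reads of HLA and MIC genes, which are close paralogs, are uncertain.

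On MHC class II, 2 of 8 members rose: CTSS, a cathepsin that trims the invariant chain, from 0.413 ± 0.259 to 11.4 ± 1.99 RPKM, and CD74, the invariant chain, 2.44-fold (camera adjusted p = 0.356; over the list alone, 2 rose). With the neighbours' median removed, 5 MHC class II members rose. The 3 gained, named after their values were seen, were low in both lines. HLA-DPA1 had 14, 15 and 19 reads in WT and 12, 24 and 13 in MUT. HLA-DPB1 had 8, 12 and 25 against 9, 15 and 13, and HLA-DMA 56, 64 and 98 against 121, 80 and 35. On the deposited scale, which compresses low genes, removing a lower neighbours' median can itself give such a rise. Of 18 checkpoint and immune-evasion ligands, CD59 rose and TNFSF9 and TNFSF4 fell (camera adjusted p = 0.973; over the list alone, 1 rose and 2 fell). The checkpoint list mixes ligands of unlike roles, not all of which hold back immune cells. Its median was -0.01, its mean -0.05 and its camera direction higher. CD274, the gene of PD-L1, was 0.761 ± 0.283 RPKM in WT and 1.14 ± 0.684 in MUT (log2 fold change 0.25, SE 0.23, adjusted p = 0.54), and it lies among neighbours that were lower in MUT. CD74 lost its call without WT replicate 3 or MUT replicate 3 (adjusted p up to 0.071). CD59, TNFSF9 and TNFSF4 lost theirs without MUT replicate 3, CD59 also without WT replicates 1 and 3 and MUT replicate 2, and TNFSF4 also without WT replicates 2 and 3 and MUT replicate 1 (adjusted p up to 0.121).

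**Figure D3:**
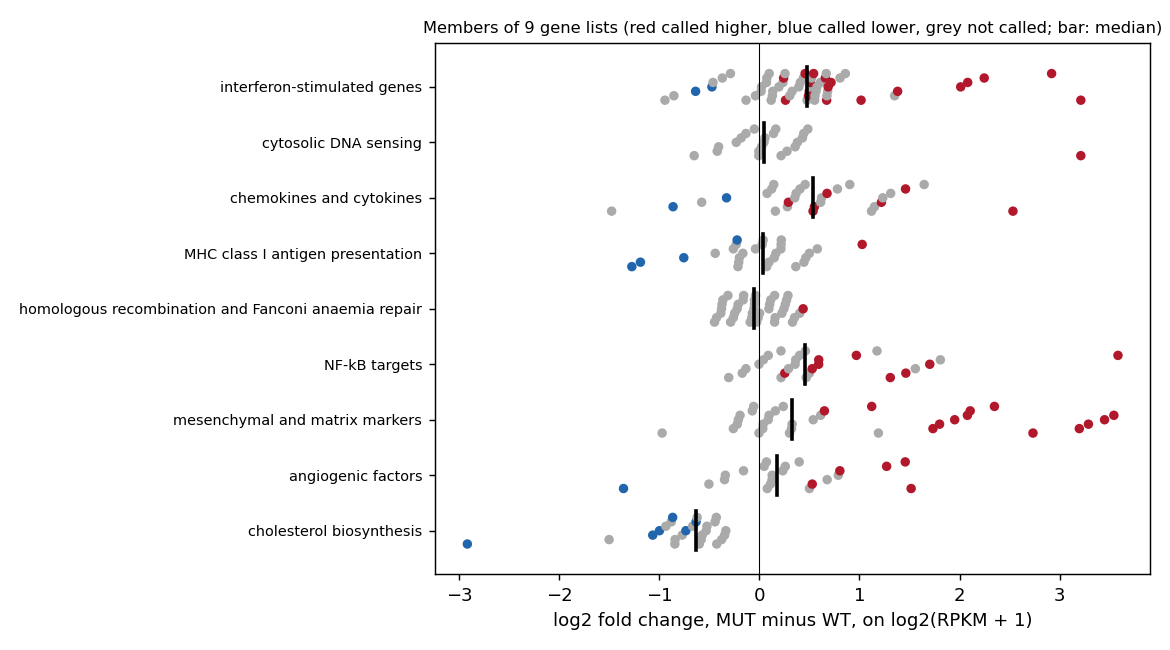
Log2 fold change (x axis, MUT minus WT on log2(RPKM + 1)) of each tested member of 9 gene lists, with red points called higher, blue points called lower, grey points not called and a black bar at the list's median. The medians are 0.48 for interferon-stimulated genes, 0.05 for cytosolic DNA sensing, -0.05 for homologous recombination and Fanconi anaemia repair and -0.63 for cholesterol biosynthesis.

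Genes of homologous recombination and Fanconi anaemia repair, the pathway of BRCA1, were not called as a group. Of 39 tested members limma called 1 higher and left 38 uncalled, with 11 at an unadjusted p under 0.05 (median log2 fold change -0.05, camera adjusted p = 0.791; none called when adjusted over the list alone). The member that rose was NBN, a subunit of the complex that senses DNA breaks, from 17.2 ± 1.03 to 23.6 ± 0.956 RPKM, and its call was lost without each library in turn (adjusted p up to 0.17). Of 23 genes of end joining and PARP-dependent repair, PARP3 rose 1.79-fold and RNF8 fell 2.50-fold (camera adjusted p = 0.898; over the list alone, 1 rose and 1 fell). The end joining list had a median of 0.04, a mean of -0.02 and a camera direction of higher. Of 28 p53 targets, PHLDA3, CCNG1 and MDM2 fell (camera adjusted p = 0.573; over the list alone, 3 fell). PHLDA3, an inhibitor of AKT signalling, fell from 0.966 ± 0.152 to 0.135 ± 0.0674 RPKM. Of 33 proliferation genes, CDC6, which licenses replication origins, fell 1.57-fold (camera adjusted p = 0.573; none over the list alone, with 7 at an unadjusted p under 0.05 by limma). Without MUT replicate 1, 2 genes of the end joining list rose, and 3 did with scaling by library size only. With the GC trend removed, 2 recombination and 4 proliferation genes fell. RNF8 lost its call without MUT replicate 3 (adjusted p = 0.0529). PARP3, CCNG1, MDM2 and CDC6 each lost theirs without at least 4 of the 6 libraries in turn, MUT replicate 3 among them (adjusted p up to 0.101, 0.128, 0.158 and 0.132).

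Mesenchymal and matrix markers were higher in MUT by camera (adjusted p = 2.56e-06; with an estimated correlation, adjusted p = 0.12). Of 33 tested members 13 rose, none fell and 20 were not called. Collagen VI chains COL6A1 and COL6A2 were 0.114 ± 0.0773 and 0.0612 ± 0.0319 RPKM in WT and 13.4 ± 7.55 and 11.3 ± 7.71 in MUT. MMP2, a matrix metalloprotease, rose from 0.140 ± 0.0875 to 11.7 ± 3.38 RPKM, and VIM, the intermediate filament of mesenchymal cells, from 0.809 ± 0.2001 to 15.6 ± 1.54 RPKM. The median log2 fold change was 0.33, and 0.87 on recovered reads. Adjusted over the list alone, 15 rose. The number of members that rose was 7 of 32 tested without WT replicate 3, 6 of 31 without MUT replicate 3 and 10 or 11 without any other library. COL6A1, MMP2 and VIM kept their calls without any 1 library. As markers of other cell types, 2 of 7 fibroblast genes rose (COL1A2 and THY1, both also in the mesenchymal list) and PDPN fell (camera adjusted p = 0.762; over the list alone, 2 rose and 2 fell). COL1A2 lost its call without each library but MUT replicate 1 (adjusted p up to 0.105), and PDPN without WT replicates 2 and 3 and MUT replicate 3 (up to 0.0889). With the neighbours' median removed PDPN was no longer called lower.

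Epithelial markers split, with 4 of 32 raised, 4 lowered and 24 not called. EHF rose 53.9-fold and MUC1, a mucin of epithelial surfaces, rose from 1.59 ± 0.551 to 10.1 ± 1.99 RPKM. LAMA3, a laminin chain, rose 2.35-fold and lost its call without WT replicates 1 and 3 and MUT replicate 3 (adjusted p up to 0.0828). The 4 that fell, named after their values were seen, were the tight junction protein OCLN, from 4.85 ± 0.138 to 2.77 ± 0.1995 RPKM, GRHL1, OVOL1 and CDS1. Each of them lost its call without WT replicate 1, WT replicate 3 or MUT replicate 3, and OCLN, OVOL1 and CDS1 also without WT replicate 2 (adjusted p up to 0.179). OVOL1 and CDS1 lost it without MUT replicate 1 as well, and OVOL1 without MUT replicate 2. The list's median was -0.27, its mean 0.05 and its camera direction lower (adjusted p = 0.307), and over the list alone 4 rose and 7 fell. With scaling by library size only, and with no filter, 2 fell. Of 12 serous ovarian lineage markers, MECOM, a transcription factor, rose 3.75-fold (camera adjusted p = 0.573; over the list alone, 2 rose and 1 fell). Of 7 mesothelial markers, BNC1, CALB2 and UPK1B rose and UPK3B fell from 3.31 ± 0.401 to 0.590 ± 0.338 RPKM (camera adjusted p = 0.0876; over the list alone, 4 rose and 1 fell). BNC1 lost its call without WT replicates 2 and 3 and MUT replicate 3 (adjusted p up to 0.0755) and UPK1B without WT replicate 3 (0.0522). Without any 1 MUT library fewer than 3 of that line are left, so CALB2 and UPK1B could not reach the minimum CPM in 3 libraries and were not tested there. BNC1 and UPK1B lie among neighbours that were higher in MUT, and with these removed BNC1 kept its call and UPK1B did not (adjusted p = 0.0608). The number of mesothelial markers that rose was 1 of 7 without WT replicate 3, 1 of 5 tested without MUT replicate 1 and 0 of 5 without MUT replicate 3.

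Angiogenic factors were higher in MUT as a group by camera (adjusted p = 0.0129; with an estimated correlation, adjusted p = 0.467). Of 22 tested members 5 rose, 1 fell and 16 were not called. VEGFA, the main endothelial growth factor, rose from 3.16 ± 0.275 to 6.33 ± 1.26 RPKM (log2 fold change 0.80, SE 0.15, adjusted p = 0.022). Its co-receptors NRP1 and NRP2 rose 7.87-fold and 3.55-fold, and FGF2 rose from 0.175 ± 0.0248 to 1.85 ± 0.377 RPKM. VEGFC, named after its value was seen, rose from 0.166 ± 0.0916 to 0.686 ± 0.187 RPKM. EPAS1, the hypoxia-inducible factor HIF-2 alpha, fell from 20.7 ± 2.36 to 7.51 ± 1.30 RPKM. Adjusted over the list alone, 6 rose and 1 fell. VEGFA lost its call without any 1 WT library or MUT replicate 3 (adjusted p up to 0.0873), NRP1 without MUT replicate 3 (0.0508), and VEGFC without WT replicates 1 and 3 and MUT replicate 3 (up to 0.0989). The number of members that rose was 3, 4 and 3 without WT replicates 1, 2 and 3, and 6, 5 and 2 without MUT replicates 1, 2 and 3.

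Genes of cholesterol biosynthesis were lower in MUT by camera (adjusted p = 9.47e-08; with an estimated correlation, adjusted p = 0.467), and none of the 25 tested members had a log2 fold change above 0. The test called 6 lower and left 19 uncalled. LSS, which closes the sterol rings by forming lanosterol, fell from 13.3 ± 1.87 to 6.30 ± 1.92 RPKM, and DHCR7, the last enzyme of cholesterol synthesis, from 77.3 ± 14.5 to 41.9 ± 7.90 RPKM. The median log2 fold change was -0.63. Adjusted over the list alone, 14 fell. LSS and DHCR7 lost their calls without WT replicate 1, WT replicate 3 or MUT replicate 3, LSS also without WT replicate 2 and DHCR7 also without MUT replicates 1 and 2 (adjusted p up to 0.125 and 0.118). The number of members that fell was 1, 9 and 1 without WT replicates 1, 2 and 3, and 5, 3 and 1 without MUT replicates 1, 2 and 3. It was 12 with the GC trend removed and 3 with no filter on low values. The mean deviation of the list's genes from their means over all libraries was 0.56, -0.03 and 0.64 in WT replicates 1 to 3 and -0.44, -0.39 and -0.34 in MUT replicates 1 to 3, so that WT replicate 2 lay between the groups.

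Of 24 genes of hypoxia and glycolysis, HK2, PFKFB3 and PFKFB4 fell (camera adjusted p = 0.105; over the list alone, 3 fell). HK2, a hexokinase, fell from 61.4 ± 18.3 to 24.2 ± 3.45 RPKM. Of 25 genes of the unfolded protein and integrated stress response, HSP90B1, an endoplasmic reticulum chaperone that lies among neighbours that were higher in MUT, rose 1.67-fold (camera adjusted p = 0.578; over the list alone, 1 rose), and was not called with the neighbours' median removed (adjusted p = 0.194). Of 27 immediate-early and heat-shock genes, KLF4 rose 1.57-fold (camera adjusted p = 0.973; none over the list alone, with 3 at an unadjusted p under 0.05 by limma), with a median of -0.14, a mean of -0.08 and a camera direction of higher. Each of these 5 genes lost its call without 3 or more of the libraries in turn, MUT replicate 3 among them (adjusted p up to 0.157), and without MUT replicate 2, 2 immediate-early genes rose. With the GC trend or the neighbours' median removed, 3 immediate-early genes rose. Without WT replicate 1 and without MUT replicate 3 the hypoxia list was called (camera adjusted p = 0.0103 and 0.00792).

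Among signs of RNA quality, 1 of 13 mitochondrially encoded transcripts fell, MT-ND6, from 2092 ± 625 to 822 ± 131 RPKM (camera adjusted p = 0.316; over the list alone, 2 fell). Of 41 cytosolic ribosomal protein genes RPS23 fell 1.51-fold (camera adjusted p = 0.553; none over the list alone, with 8 at an unadjusted p under 0.05 by limma). RPS23 lies among neighbours that were lower in MUT and was not called with their median removed (adjusted p = 0.276). limma called none of 13 replication-dependent histone genes, with 3 at an unadjusted p under 0.05 (camera adjusted p = 0.422; none over the list alone, and none by limma-voom). Without WT replicate 1 the mitochondrial and histone lists were called lower (adjusted p = 0.0398 and 0.0053), and 2 mitochondrial, 2 ribosomal protein and 1 histone gene fell. Of 8 leukocyte markers LCP1, an actin bundling protein, rose from 2.55 ± 0.832 to 21.9 ± 4.04 RPKM, and ITGB2 and CD14 fell (camera adjusted p = 0.864; over the list alone, 2 rose and 2 fell). Of 10 endothelial markers CDH5, the cadherin of endothelial junctions, rose from 0.661 ± 0.105 to 6.72 ± 0.964 RPKM (camera adjusted p = 0.316; over the list alone, 3 rose and 1 fell). MT-ND6 and RPS23 lost their calls without WT replicates 2 and 3 and MUT replicates 1 and 3 (adjusted p up to 0.118 and 0.14), ITGB2 without WT replicate 3 and MUT replicate 3 (up to 0.0677), and CD14 without MUT replicate 3 (0.0596). The number that rose was 2 for leukocyte markers without MUT replicate 1, and 2 for endothelial markers without MUT replicate 1 and without MUT replicate 2. Without WT replicate 3, 1 endothelial marker fell. With all 6 libraries 3 rose by limma-voom, with a pseudocount of 0.1 RPKM and with the GC trend or the neighbours' median removed. All of these settings but the last also called 1 lower, FLT1, with 370, 242 and 1256 reads in WT and 17, 35 and 3 in MUT. With the neighbours' median removed the 2 gained were low. They and FLT1 were named after their values were seen. TEK had 4, 6 and 16 reads in WT and 11, 14 and 7 in MUT. TIE1 had 26, 9 and 47 against 116, 42 and 46.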

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

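The pseudocount, thinning, GC and neighbour settings were chosen after seeing the data. BRCA1 kept its direction and its call under each alternative run, with log2 fold changes of -2.71 to -2.31 when 1 library was left out. The count of 1673 called genes (957 higher, 716 lower) stayed within 1.5 times under the other scalings, filters, limma-voom (1866) and the added settings. Of the 1673, 1079 were called with the neighbours' median removed (1475 called), 1 of them in the opposite direction, and 1383 to 1648 in the others of these settings. It was 123 (93 and 30) in a test against a 1.5-fold change and 377 (248 and 129) at an adjusted p under 0.01, which follow from stricter tests. With 1 library left out it ranged from 293 to 1264 (204 to 766 higher, 89 to 523 lower). With the replicate block it was 556 (354 and 202), 537 of them among the 1673, and no list call changed, while 8 interferon-stimulated, 8 mesenchymal and 3 angiogenic genes rose. Deviations of same-numbered libraries correlated across genes at 0.609, -0.376 and -0.089, so the numbers were not taken as pairs, and not every library correlated best with its own number. Camera called 6 lists, and 0 with an estimated correlation (2 at an unadjusted p under 0.05): adjusted p = 0.467 for interferon-stimulated, chemokine, angiogenic and cholesterol genes, 0.241 for NF-kB targets and 0.12 for mesenchymal markers. Angiogenic factors (0.0129) missed an adjusted p of 0.01. With 1 library left out, 6 to 9 lists were called, with adjusted p of 0.00792 to 0.568 for hypoxia, 0.0398 to 0.645 for mitochondrial and 0.0053 to 0.898 for histone genes, the last also at 0.0124 with no filter. Fry, which does not compare a list with other genes, called 12 lists directionally, adding DNA sensing and endothelial markers (0.0095), RNA sensing (0.00661), MHC class II and p53 targets (0.0442) and mesothelial markers (0.04). Its mixed test called 25, adding DNA sensing and p53 (6.24e-07), RNA sensing (0.0011), interferons (3.23e-05), MHC class I (6.24e-06) and II (0.000173), checkpoint ligands (0.000675), recombination and epithelial (2.38e-06), end joining (1.11e-05), proliferation (0.00791), lineage (1.55e-05), unfolded protein (1.65e-05), hypoxia (0.0371), ribosomal (0.0112), leukocyte (8.54e-05), endothelial (5.05e-05), fibroblast (0.000113) and mesothelial (3.68e-05) lists. Mesothelial markers were called with a pseudocount of 0.1 RPKM (0.05 after rounding) and with the GC trend removed (0.0254). MHC class II (9.38e-06) and endothelial markers (0.0442) were called with neighbours removed, a setting that can raise low genes whose neighbours were lower in MUT. Over the 11 settings that leave in every library, without a stricter test or the block, the number of members that rose or fell moved by over 1.5 times in 21 of 28 lists, by 1 gene in 10 of them and by more in 11. Except where a setting is itself a stricter test or has fewer samples, the cause was not tested. Of 80 other named and called genes, 45 lost their call without at least 1 library and 34 kept it without each library in turn. The other 1, CALB2, kept it where tested. Without a MUT library it could not reach the minimum CPM in 3 libraries. None of the 83 tested reversed. The planned DESeq2 test was not run because the values are not counts. CCL5 and IFNB1 missed the read minimum at their low level, CCL5 also in the deepest library, and had at most 20 reads in any library. With no filter they did not pass the test (adjusted p = 0.221 and 0.0981).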

Other observations

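Some genes were present in one line and nearly absent from the other. Above 1 RPKM in all 3 libraries of one group and under 0.1 RPKM in all 3 of the other were 15 genes in MUT and 6 in WT, and none of the 9 other ways to split the libraries into 3 and 3 gave any such gene. Those splits mix the lines on both sides, so genes that differ between the lines could not count there. Among the 15 were ARMCX2, BCHE, CALB2, CECR1, COL6A2, CPED1, CSTA, EVC, FOLR2, IFI16, LHX1, LIN28B, PDE2A and RYR2, and the 6 were CYP8B1, MYH14, NOTUM, PTF1A, SMR3B and WBSCR17. They were chosen after their values were seen. RYR2, a calcium release channel of heart muscle, had 67, 69 and 72 reads in WT and 5670, 2557 and 1335 in MUT, and LIN28B, which blocks let-7 maturation, had 6, 3 and 2 against 674, 538 and 316. PTF1A, a transcription factor of pancreas development, had 274, 149 and 163 reads in WT and 11, 1 and 2 in MUT.

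The test of windows per library and the count of list members that reach 2 RPKM only through MUT were chosen after the results were seen; the other tests were set out before their results. limma called 1673 genes in the real split and at most 0 in the other 9 of 10 splits of the 6 libraries, with 4042 genes at an unadjusted p under 0.05 in the real split and 10 to 1531 in the others. 10 splits (1 as large, the real one) are too few for a share under 0.05. The other splits put libraries of both lines on each side. Differences between the lines count as spread there, so the lack of calls in them says little.

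Neighbouring genes moved together. The medians of 266 windows of neighbouring genes had an SD of 0.237 on the log2 scale, above the 0.088 that 1000 shuffled gene orders reached, and it was 0.225 after each library's GC trend was removed, against 0.083 when shuffled, which argues against random order and against GC content as the whole cause. The narrowest pair of libraries across groups had an SD of 0.227 and the widest pair within a group, MUT replicates 1 and 2, 0.378, so window medians also differ between libraries of 1 line. Over that spread, limma was run on each window's median per library, which is not the median of its genes' fold changes. It called 32 windows, 14 higher and 18 lower (78 at an unadjusted p under 0.05). With the GC trend removed it called 56. In other splits it called at most 0 (0 to 37 unadjusted), but those splits mix the lines on each side, so this says little. Among the 32, chosen after their values were seen, were AMDHD1 to CKAP4 (log2 fold change 0.62) and ZNF346 to TRIM52 (-0.76). A called window need not hold genes that moved together: SYAP1 to BCOR was called lower (-0.56), but its genes' median log2 fold change was 0.04. Of the 15 windows whose median of fold changes lay beyond every shuffled order, 10 were called. A candidate explanation is a different copy number of these blocks in the 2 lines: in windows chosen on odd-placed genes, a median of 88% of even-placed genes lay on the window's side, but only 5 windows were chosen, under a minimum of 10 that was itself set after few had been seen, so copy number and other regional changes cannot be told apart.

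Interferon-stimulated genes were higher in MUT, and the list's call was lost with an estimated correlation (adjusted p = 0.467). With the neighbours' median removed the list's median was 0.43, against 0.48 before, with a camera adjusted p of 4.89e-08 at the preset correlation. These values argue against such blocks as the whole cause. This removal can itself raise low genes whose neighbours were lower in MUT. That limits the argument for the 27 members with a mean under 2 RPKM. Genes with few reads stay open as a cause: the median was 0.47 among the 30 members with a mean of at least 2 RPKM and 0.48 among the 27 under it, but 7 of the 30 reach 2 RPKM only through MUT, so the change itself sorts them. Loss of BRCA1 function may raise these genes, but the design has 1 pair of lines, and divergence of the 2 lines for other reasons was not tested.

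Some libraries of opposite groups shared deviations from their group means. Across genes, the deviations of WT replicate 3 and MUT replicate 2 correlated at 0.736. Those of WT replicate 1 and MUT replicate 1 correlated at 0.609 and those of WT replicate 2 and MUT replicate 3 at 0.595. Genes are not independent replicates here. These pairs were picked as the highest, and the other pairs across groups lay between -0.704 and 0.107. Deviations of a group's libraries from its mean cancel out for each gene, so the correlations constrain each other and are not separate observations. The correlation of WT replicate 3 and MUT replicate 2 was 0.732 after each library's GC trend was removed. It was 0.723 after thinning to the shallowest library. For this pair, these values argue against GC content or depth as the whole cause. A shared culture or library batch could give this pattern, but the labels used here name none, and no biological explanation was tested.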
